A study of Homo sapiens with 85 samples.

How the data were processed

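Airway epithelial cells were taken by bronchial brushing, and RNA and DNA were extracted one after the other from the same material with a column kit, per the labels' protocols. The library protocol is not given in the sources used here, and the counting of reads by strand is not stated, so a gene and its antisense partner cannot be separated. The submitters' processing notes name BWA, bedtools and the genome build hg19, with no versions. The deposited values are normalized counts that the authors rounded to whole numbers, treated here as a score with no fixed unit, since neither the labels nor the file give the normalization method. The values themselves show a scaling: the 75th percentile over genes varied by only 0.697% (CV) between libraries, around 1206, with totals of 18187044 to 22000473. They are not raw counts, so no count model was used, although the plan fixed beforehand named one for the case of raw counts. The plan's branch for normalized values on a linear scale was followed in its place.

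The table held 16535 Ensembl gene identifiers, of which 16458 were matched to a symbol by identifier. List members under another name were matched through RefSeq synonyms. Of the identifiers, 16499 were found in GENCODE release 29, 0 of them on the X, Y or mitochondrial chromosomes, and the other 36 have no chromosome here. The reference is of another build than the files and was used only for names and chromosomes, and no positions are given. Every column of the table was matched to a sample by its name. The groups are the 57 asthma and 28 control samples of the labels. The highest Spearman correlation of any 2 libraries was 0.9917, and no library was counted as a copy of another.

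Depth was sought in the low values. A library whose counts were scaled up by more than 1 and then rounded skips whole numbers, and a comb of that spacing was fitted to the genes with values of 1 to 30 in each library. A factor above 1.15 with a gain in log likelihood above 10 was called, limits set after seeing the values. In 16 libraries (11 asthma, 5 control, Fisher's exact p = 1.0) the factor was between 1.20 and 2.26, so these were sequenced less deeply than the common scale. A factor above 1.15 was also fitted to 2 further libraries (asthma) that missed the limit for the gain, at least 1 of which skips whole numbers too, so 16 is a lowest number. On simulated data, 20 of 20 scaled-up libraries were called, all within 5% of the true factor, and 0 of 20 others. The simulated noise was of the kind the fit assumes, so these rates need not hold for the real libraries. Asthma libraries 12 and 40, not called, had only 65 and 104 genes at 1, against 294 and 424 at 2. Among controls not called, the fewest genes at 1 were 266. More asthma libraries may thus be scaled up, and the Fisher test covers only the called ones. For the remaining libraries the depth is unknown, and no interval for counting error can be given.

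Genes with a value above 1 in at least 28 libraries, the size of the control group, were kept, which left 16312. This is a reading of the planned filter, whose wording was ambiguous. Values were transformed as log2(value + 1), and a fold change on that scale understates the change of low genes. Asthma and control were compared with limma 3.58.1 in R 4.3.3 (trend across the mean, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05), with no covariates because the labels give none. Data were simulated with the real means and spreads for 57 and 28 libraries, 16312 genes and 200 changed genes. There 73% of changes of 0.5 and 96% of changes of 1 on the log2 scale were recovered, and 9 of 178 calls were false. The simulated genes varied independently of each other, with the same spread in both groups. Real genes vary together (estimated inter-gene correlation 0.66 for the monocyte and macrophage list), so these rates need not hold for the real data. Named are the 12 called genes with the largest fold change in each direction, up to 4 members with the smallest p of each list called by camera, and a panel of 28 genes, 95 genes in all, of which 1 is not reported here.

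Gene lists for 32 cell types and pathways, with the panel, the filter and the tests, were fixed before the data were examined. Lists were tested with camera (preset inter-gene correlation 0.01, and an estimated one), with fry, which asks whether the genes of a list move on balance in one direction, and with a two-sided permutation test of the list score (100000 resamples). Intervals of score differences are 95% bootstrap intervals from 10000 resamples. Spread was compared by the absolute deviation from the group median with 100000 permutations. Relations were computed within each group with the members shared by both lists left out, with permutation p and Benjamini-Hochberg adjustment over 16 relations. Whether the type 2 scores fall into clusters was examined with mclust 6.1.1. In that package a larger BIC is the better one. The BIC of a mixture of 2 components minus that of 1 was -1.72 in asthma and -6.67 in controls, so 1 component had the better BIC. In asthma the margin is small and does not settle whether clusters exist. The scores were not split. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 read the low values, and matplotlib 3.10.9 drew the figures.

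Alternatives named beforehand were TMM factors, quantile normalization, other filters and pseudocounts, robust empirical Bayes, a rank-based transform, covariates for library complexity, cell composition and the first 2 residual components, and leaving out libraries over 3 median absolute deviations from the median in total, detected genes or correlation (3 libraries, all asthma). Chosen after seeing the data were leaving out the 16 libraries that skip whole numbers, leaving out all 18 with a factor above 1.15, the position in the table, the aryl hydrocarbon receptor score, myeloid scores and sample quality weights. The table's columns were divided after column 49, the end of the longest run of control columns. The next 9 columns are all asthma, and the groups mix from column 59 on. Before that the groups (44 asthma, 14 control) lie mostly in separate runs of columns. The first 58 and the last 27 columns (13 asthma, 14 control) were therefore compared as well. The boundary is a guess at a batch that no label gives, and other boundaries were also looked at.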

Results

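Gene expression was measured by RNA sequencing in airway epithelial cells collected by bronchial brushing, a sampling of the lining of the bronchi through a bronchoscope. The series held 85 samples, 57 from people with asthma and 28 from controls without it. Each sample was represented by a column of normalized read counts for 16535 genes, and the total per sample ran from 18187044 to 22000473. Totals did not differ between the groups (permutation p = 0.125), nor did the share of the total taken by the 50 largest genes (permutation p = 0.67). The number of genes above 0 averaged 16118 ± 125.9 in asthma and 16174 ± 110.4 in controls (SD, permutation p = 0.0508). These totals are sums of scaled values and do not give the sequencing depth, which is unknown for most libraries. The disease label is the only difference between samples that the labels give, so age, treatment, smoking and processing day could not be entered in any model. The labels do not state that each sample came from a different person, and the p-values measure the spread between these samples.

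The first comparison asked which genes differed between asthmatic and control airway epithelium. Genes of several unrelated functions were higher in asthma, led by PHACTR3, a regulator of protein phosphatase 1 and actin, SLCO1B3, an organic anion transporter, PRR4, a proline-rich secretory protein of glands, and WNT16, a Wnt ligand. Among the genes that were lower were IL1B, the gene of interleukin-1 beta, MPEG1, which encodes a pore-forming protein of macrophages, and CX3CR1, the fractalkine receptor. Of 16312 genes tested with limma on log2(value + 1), 50 passed a Benjamini-Hochberg adjusted p of 0.05, 23 of them higher and 27 lower in asthma. Most of the 50 lay below the median of the gene means. Among the genes above it, tested alone, limma called 2 (693 unadjusted). At an unadjusted p of 0.05, 1693 genes passed, or 10.4% of those tested, and the median log2 fold change over all genes was -0.0034.

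PRR4 (ENSG00000111215) averaged 987 ± 1464 normalized counts in asthma and 200.4 ± 174 in controls (SD). Its log2 fold change was 1.68 ± 0.34 (SE, limma adjusted p = 0.00884), and 52 of the 57 asthma samples lay above the control median. SLCO1B3 (ENSG00000111700) rose from 3.93 ± 3.16 to 22.2 ± 36.3 normalized counts, a log2 fold change of 1.68 ± 0.32 (limma adjusted p = 0.00884). PHACTR3 averaged 222 ± 300 in asthma against 36.6 ± 29.5 in controls, a log2 fold change of 1.70 ± 0.40 (limma adjusted p = 0.0309). WNT16 rose by 1.44 ± 0.30 on the log2 scale and was above the control median in 51 of the 57 asthma samples. The other genes among the 12 with the largest increases had log2 fold changes from 0.79 to 1.10. They were PTCHD4, GAS1, a growth-arrest protein and hedgehog co-receptor, ADAMTS9, a matrix metalloprotease, ZSWIM2, PCAT19, SLC24A3, a sodium and calcium exchanger, ITGA10, an integrin subunit, and SIGLEC8. SIGLEC8 encodes a surface receptor of eosinophils and mast cells and rose from 10.2 ± 6.78 to 22.8 ± 15.2 normalized counts (log2 fold change 0.99 ± 0.23, limma adjusted p = 0.0303). Low genes such as ZSWIM2, at 2.84 ± 2.27 against 1.07 ± 1.41, had their fold changes compressed by the added 1.

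Among the genes that fell, B3GAT1 (ENSG00000109956), a glucuronyltransferase that makes the CD57 epitope, went from 87.7 ± 42.9 normalized counts in controls to 44.9 ± 28.5 in asthma. Its log2 fold change was -1.03 ± 0.20 (SE, limma adjusted p = 0.00884), and 50 of the 57 asthma samples lay below the control median. IL1B fell from 117 ± 72.0 to 73.2 ± 119 (log2 fold change -1.02 ± 0.24, limma adjusted p = 0.0309), lower than the control median in 49 samples. MPEG1 went from 366 ± 106.7 to 226 ± 138 (log2 fold change -0.91 ± 0.18). FFAR2, a receptor for short-chain fatty acids on leukocytes, fell by 1.12 on the log2 scale, P2RY13, an ADP receptor, by 1.03, and CX3CR1 by 0.95. The other genes among the 12 with the largest decreases were LRRC55, TIFAB, DNASE1L3, EGR3, BCL2A1, an anti-apoptotic protein of leukocytes, and SDS, at -0.88 to -1.26. LRRC55 and TIFAB had low values, with means of 5.09 and 6.74 in asthma and 8.29 and 12.2 in controls. With scores of ciliated, basal, secretory and mixed leukocyte markers as covariates, limma called 0 genes (938 at an unadjusted p of 0.05), and without 16 libraries whose low values skip whole numbers it also called 0 (1706 unadjusted), as it did without 2 more libraries that may be scaled up too. In the first 49 columns of the table (35 asthma, 14 control) limma called 0 genes (774 unadjusted), against 482 (3768 unadjusted) in the last 36 columns (22 asthma, 14 control).

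**Figure D1:**
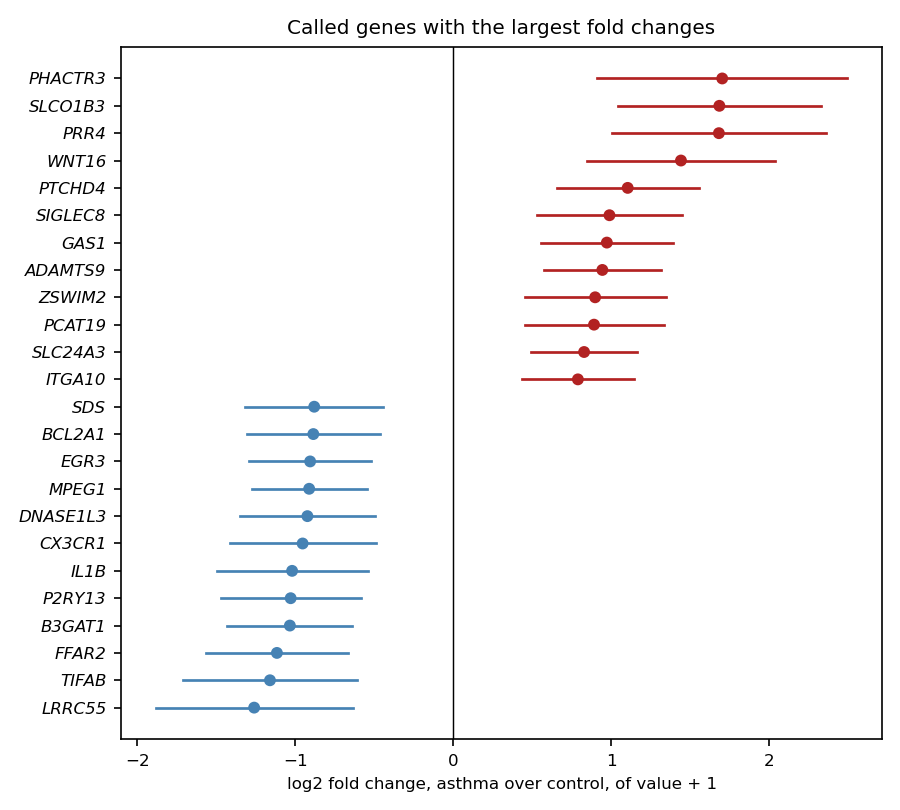
Log2 fold change of value + 1, asthma over control, for the 12 called genes with the largest increase (red) and the 12 with the largest decrease (blue). Points are limma estimates and lines their 95% confidence intervals over 57 asthma and 28 control samples. The genes were chosen by the same limma test, so no interval could reach 0.

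A panel of 28 genes long studied in asthma was read out whatever its result. CLCA1, a secreted protein of mucous cells that is induced by interleukin-13, had the largest log2 fold change of the panel. It averaged 1086 ± 2523 normalized counts in asthma and 48.3 ± 82.2 in controls. Its log2 fold change of 2.67 ± 0.69 missed the threshold over all genes (limma adjusted p = 0.0576), with 42 of the 57 asthma samples above the control median. No panel gene passed over all genes, and 6 passed when adjusted over the list alone: CLCA1, FKBP5, MUC5AC, CCL26, CST1 and CDHR3. CST1, a cystatin of the asthmatic epithelium, had a log2 fold change of 1.902 ± 0.62 (adjusted p = 0.182), MUC5AC, the main inducible airway mucin, 0.85 ± 0.26 (adjusted p = 0.146), and FKBP5, a glucocorticoid-induced co-chaperone, 0.82 ± 0.23 (adjusted p = 0.10). SERPINB2 was at 0.81 ± 0.32, CCL26, the gene of eotaxin-3, at 1.01 ± 0.33, NOS2, the inducible nitric oxide synthase, at 0.64 ± 0.33 and POSTN, the gene of periostin, at 0.63 ± 0.31, with adjusted p from 0.168 to 0.498. CLC, TPSAB1 and CPA3, genes of eosinophils and mast cells, were at 0.65 ± 0.28, 0.79 ± 0.41 and 0.66 ± 0.44. The mast cell tryptase TPSAB1 and the cystatin CST1 have near-identical copies, so their values are uncertain.

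FOXJ1, the master regulator of motile cilia, had a log2 fold change of 0.00 ± 0.09, KRT5, a basal cell keratin, 0.07 ± 0.14, and ALOX15 0.11 ± 0.13. MUC5B and the club cell gene SCGB1A1 were at -0.42 ± 0.28 and -0.41 ± 0.26. Of the genes near asthma risk variants, CDHR3 was at 0.19 ± 0.07, ORMDL3 at 0.06 ± 0.05, GSDMB at 0.10 ± 0.10, SMAD3 at -0.08 ± 0.05, IL33 at -0.27 ± 0.16 and TSLP at 0.18 ± 0.19. The DNA methyltransferases DNMT1, DNMT3A and DNMT3B and the demethylase TET1 differed by 0.00 ± 0.06, -0.05 ± 0.06, 0.05 ± 0.08 and 0.05 ± 0.14. CXCL8 and IFIT1, at -0.07 ± 0.17 and -0.29 ± 0.16, complete the panel.

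The next comparison asked whether groups of genes that mark a cell type or a pathway moved together. Markers of the type 2 epithelial response, the program induced by interleukin-4 and interleukin-13, and of the glucocorticoid response were higher in asthma. Markers of neutrophils and of dendritic cells were lower. The score of a list, the mean log2(value + 1) of its members, differed by 0.70 ± 0.19 (SE) for type 2 and 0.35 ± 0.08 for glucocorticoid response, and by -0.51 ± 0.13 for neutrophils and -0.49 ± 0.12 for dendritic cells. These 4 of the 32 lists passed a permutation test of the sample labels, but camera with an estimated inter-gene correlation called 0 lists, and fry called 4. Camera with a preset inter-gene correlation of 0.01 called 12 lists, 5 higher and 7 lower. With covariates it called 7 higher and 4 lower of 23 lists (cell composition), and 10 higher and 4 lower of 29 (myeloid scores). The lists used as covariates were not tested there. They include the neutrophil, monocyte and macrophage, and dendritic cell lists, which are among the 7 lower ones. The smaller count of lower lists thus cannot be read as an effect of the covariates. The lists called higher were all still tested. At an unadjusted p of 0.05, camera with the preset correlation passed 13 lists.

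The type 2 list had 23 measured members, 20 of them with a positive fold change and none past the threshold over all genes, while 10 were higher when adjusted over the list alone. Its score passed the permutation test (adjusted p = 0.019) and camera (adjusted p = 2.61e-09), but had adjusted p = 0.11 with an estimated correlation, and 40 of the 57 asthma samples lay above the control median. CDH26, an epithelial cadherin induced by interleukin-13, had a log2 fold change of 0.48 ± 0.14 and CST4 one of 1.68 ± 0.53. CST4 belongs to a cluster of similar cystatin genes and is uncertain for that reason. The glucocorticoid list had 15 measured members, none called over all genes and 7 higher when adjusted over the list alone. Its permutation adjusted p was 0.010, with adjusted p = 0.0835 with an estimated correlation, and 44 of the 57 asthma samples were above the control median. ALOX15B, a lipoxygenase, was at 1.41 ± 0.36 (limma adjusted p = 0.0518), FKBP5 at 0.82 ± 0.23, TFCP2L1 at 0.59 ± 0.20 and RGS2 at 0.39 ± 0.15.

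Of 14 dendritic cell markers, CLEC10A, a lectin of conventional dendritic cells, fell over all genes (log2 fold change -0.86 ± 0.21, limma adjusted p = 0.0464), and 9 were lower when adjusted over the list alone. The score was below the control median in 45 of the 57 asthma samples, with permutation adjusted p = 0.010 and adjusted p = 0.0835 with an estimated correlation. CD83, CCL22 and FCER1A were at -0.70 ± 0.21, -0.64 ± 0.21 and -0.75 ± 0.25. Of 15 neutrophil markers, none passed over all genes and 7 were lower when adjusted over the list alone. The score was below the control median in 46 asthma samples (permutation adjusted p = 0.010, adjusted p = 0.0835 with an estimated correlation). FCGR3B, whose sequence is nearly that of FCGR3A and whose value is uncertain, was at -0.85 ± 0.23, AQP9, a water and glycerol channel, at -1.03 ± 0.29, CSF3R, the G-CSF receptor, at -0.68 ± 0.19 and CXCR2 at -0.57 ± 0.20. In the first 49 columns of the table the type 2, glucocorticoid, neutrophil and dendritic cell differences were 0.66, 0.34, -0.44 and -0.24 (permutation adjusted p from 0.221 to 0.626). In the last 36 columns they were 0.84, 0.35, -0.62 and -0.77, with adjusted p of 0.0296, 0.126, 0.0267 and 0.0145. Without the 16 libraries that skip whole numbers the glucocorticoid list passed (difference 0.37, adjusted p = 0.032), and the type 2, dendritic cell and neutrophil lists, at 0.73, -0.41 and -0.32, had adjusted p of 0.0582, 0.08 and 0.232. With those 2 more libraries left out (18 in all) the type 2 and dendritic cell lists passed (0.757 and -0.432, adjusted p = 0.0428 for each), the glucocorticoid list passed (adjusted p = 0.0288), and the neutrophil list did not (adjusted p = 0.231). With dendritic cell, neutrophil and monocyte scores as covariates the type 2 and glucocorticoid lists lost their call (0.486 and 0.247, adjusted p = 0.146 and 0.107). With the planned ciliated, basal, secretory and mixed leukocyte scores as covariates both lists kept it (0.579 and 0.295, permutation adjusted p = 0.0427 for each).

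**Figure D2:**
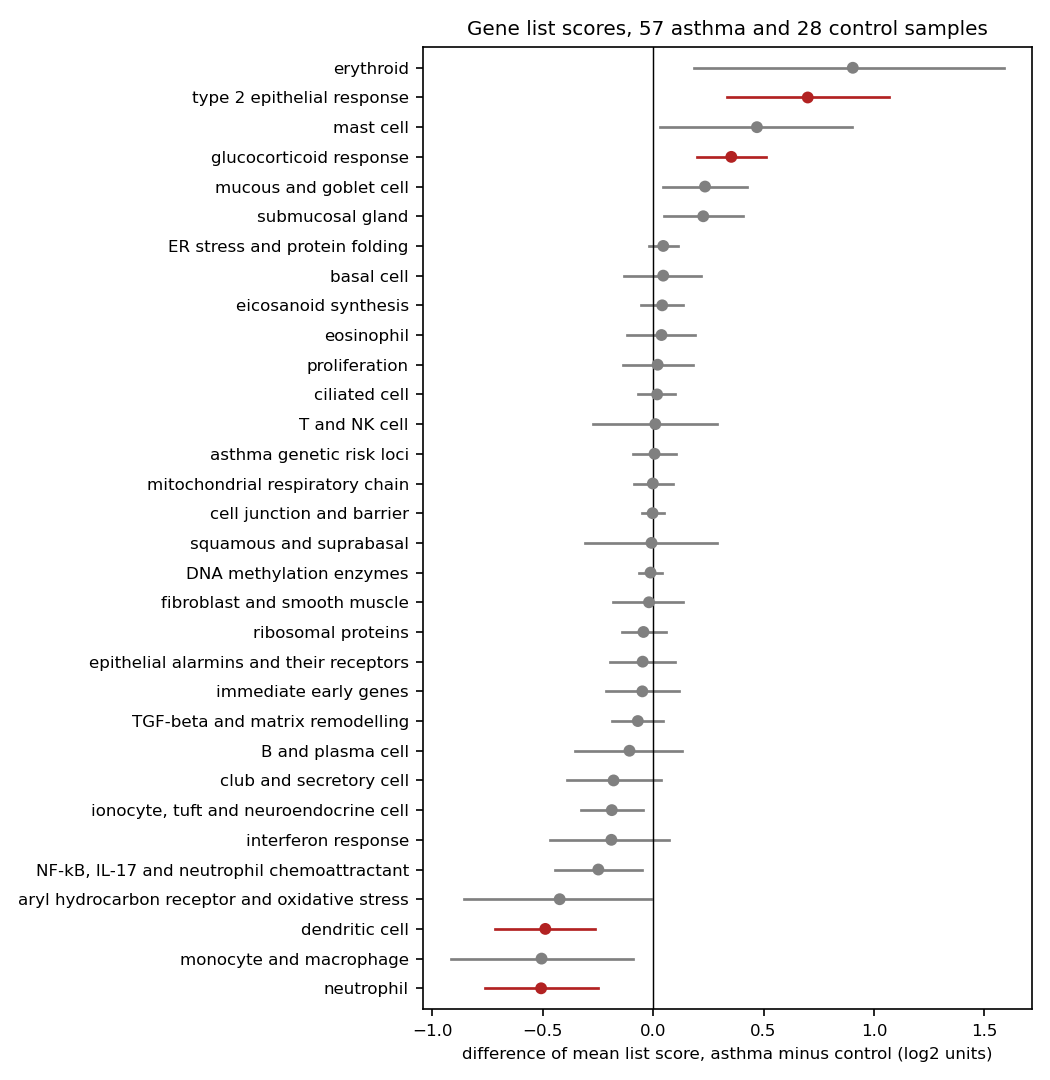
Difference of the mean list score, asthma minus control, in log2 units for 32 gene lists, over 57 asthma and 28 control samples. Points are differences and lines 95% bootstrap intervals, and the 4 lists in red had a permutation adjusted p under 0.05.

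The other 8 lists called by camera with the preset correlation lost the call in the permutation test and with an estimated correlation. The mast cell score was 0.47 ± 0.22 higher (permutation adjusted p = 0.138, adjusted p = 0.282 with an estimated correlation), with 4 of 16 members higher when adjusted over the list alone and 0 over all genes. IL1RL1, the interleukin-33 receptor, was at 1.08 ± 0.33, GATA2 at 0.86 ± 0.33, HDC, which makes histamine, at 0.50 ± 0.19 and KIT at 0.40 ± 0.16. The mucous and goblet score was 0.24 ± 0.10 higher (adjusted p = 0.195 with an estimated correlation), with TFF3, SPDEF and CREB3L1 at 0.44, 0.32 and 0.23, and 1 of 14 members higher over the list alone. The erythroid score, which marks red blood cells, was 0.90 ± 0.36 higher (adjusted p = 0.282 with an estimated correlation). It had 2 of 5 members higher over the list alone, HBA2 and HBA1, which are near-identical to each other and uncertain, while HBB and HBD were at 0.77 ± 0.42 and 0.70 ± 0.46. The monocyte and macrophage score differed by -0.51 ± 0.22, with all 13 members negative, 2 of them lower over the list alone, and adjusted p = 0.28 with an estimated correlation. CD14, CSF1R, CD68 and TREM2 were at -0.44, -0.52, -0.50 and -0.55.

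The list of NF-kB and interleukin-17 targets and neutrophil chemoattractants differed by -0.25 ± 0.10 (adjusted p = 0.282 with an estimated correlation). IL1B was its only member called over all genes, and 6 of 21 were lower over the list alone, S100A9, S100A8 and CCL20 among them at -0.74, -0.79 and -1.002. The interferon list differed by -0.19 ± 0.14 (adjusted p = 0.716 with an estimated correlation), with 21 of 22 members negative and 0 lower over the list alone. IFIT2, HERC5, IFIT3 and OASL were at -0.41, -0.31, -0.34 and -0.43. The ionocyte, tuft and neuroendocrine list differed by -0.19 ± 0.07 (adjusted p = 0.282 with an estimated correlation). ATP6V1G3, a proton pump subunit of ionocytes, was at -0.74 ± 0.24 and the only 1 of 12 members lower over the list alone, with GRP and AVIL at -0.56 and 0.21.

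The aryl hydrocarbon receptor and oxidative stress list, which holds enzymes that respond to smoke and other xenobiotics, differed by -0.42 ± 0.22 with all 18 members negative (permutation adjusted p = 0.0912, adjusted p = 0.282 with an estimated correlation). HMOX1, heme oxygenase 1, which is abundant in macrophages, fell over all genes from 393 ± 179.2 to 257 ± 121 normalized counts (log2 fold change -0.60 ± 0.14, limma adjusted p = 0.0264). It was also the 1 member lower when adjusted over the list alone. CYP1A1 and CYP1B1 were at -1.44 ± 0.53 and -1.33 ± 0.51, and GCLM was at -0.26 ± 0.10. The spread of CYP1A1 and CYP1B1 was several times the mean in controls (183 ± 619 and 649 ± 1783 normalized counts) and in asthma (68.75 ± 478.3 and 152.9 ± 651.2).

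No test called the remaining lists. Ciliated cell, basal cell, squamous, and club and secretory scores differed by 0.02 ± 0.04, 0.05 ± 0.09, -0.01 ± 0.15 and -0.18 ± 0.11, and the submucosal gland score by 0.23 ± 0.09, with PRR4 its 1 of 10 members called over all genes and 2 higher and 1 lower over the list alone. T and NK cell markers differed by 0.01 ± 0.14 (95% interval -0.27 to 0.29), B and plasma cell markers by -0.11 ± 0.13, eosinophil markers by 0.04 ± 0.08 and fibroblast and smooth muscle markers by -0.02 ± 0.08. SIGLEC8 was the 1 of 12 eosinophil markers called, over all genes and over the list alone. The genetic risk loci differed by 0.01 ± 0.05, with 3 of 27 members higher and 1 lower over the list alone, the alarmins by -0.05 ± 0.08, DNA methylation enzymes by -0.01 ± 0.03, and junction and barrier genes by -0.00 ± 0.03. Eicosanoid synthesis, ER stress, proliferation and immediate early genes differed by 0.04 ± 0.05, 0.05 ± 0.03, 0.02 ± 0.08 and -0.05 ± 0.09. EGR3 was the 1 of 18 immediate early genes called over all genes, and over the list alone 2 were higher and 2 lower. Over the list alone 2 of 18 eicosanoid genes were higher and 1 lower, 1 fibroblast marker was higher, 1 alarmin gene was higher and 1 lower, and 1 TGF-beta and matrix gene was lower. Ribosomal proteins, the respiratory chain, and TGF-beta and matrix genes differed by -0.04 ± 0.05, -0.00 ± 0.04 and -0.07 ± 0.06. The median log2 fold change and the score difference had opposite signs for the T and NK, eosinophil, squamous, fibroblast, proliferation, eicosanoid, immediate early and respiratory chain lists. Camera took the sign of the median for the T and NK, squamous, fibroblast, immediate early and respiratory chain lists and that of the score for the other 3, and it gave junction and barrier genes an upward direction against a negative median and score.

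A further comparison asked whether samples within a group differed more from each other in asthma, since the study's title speaks of endotypes, subtypes that differ in mechanism. Scores of the type 2, glucocorticoid, dendritic cell, and T and NK cell lists were more spread in asthma. The SD of the type 2 score was 1.07 over 57 asthma samples and 0.66 over 28 controls, that of the T and NK score 0.86 and 0.46. The SD of the dendritic cell score was 0.71 and 0.36, and that of the glucocorticoid score 0.49 and 0.26. Each of the 4 lists had adjusted p = 0.0422 in a permutation test of absolute deviations from the group median, 7 of 32 lists passed unadjusted, and 28 of 32 had the larger deviation in asthma. A larger spread in asthma was thus not particular to these 4. The median correlation of a library with the others averaged 0.965 ± 0.0064 in asthma and 0.969 ± 0.0043 in controls (SD, difference not tested). Ribosomal proteins (SD 0.31 and 0.16, adjusted p = 0.0854) and eosinophil markers (0.49 and 0.23, adjusted p = 0.155) did not pass by absolute deviations. By the ratio of SDs 7 lists passed, these 2 (adjusted p = 0.0202 and 0.0113), the genetic risk loci (adjusted p = 0.0333) and the 4 above. The aryl hydrocarbon receptor list had its larger SD in controls, 1.04 against 0.73 (adjusted p = 0.217). Without 3 asthma libraries far from the others in total, detected genes or correlation, 0 lists passed (5 unadjusted), with adjusted p from 0.0853 to 0.087 for these 4. The differences in mean absolute deviation changed little: from 0.385 to 0.361 for type 2, 0.306 to 0.297 for T and NK, 0.261 to 0.231 for dendritic cell and 0.177 to 0.167 for glucocorticoid.

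**Figure D3:**
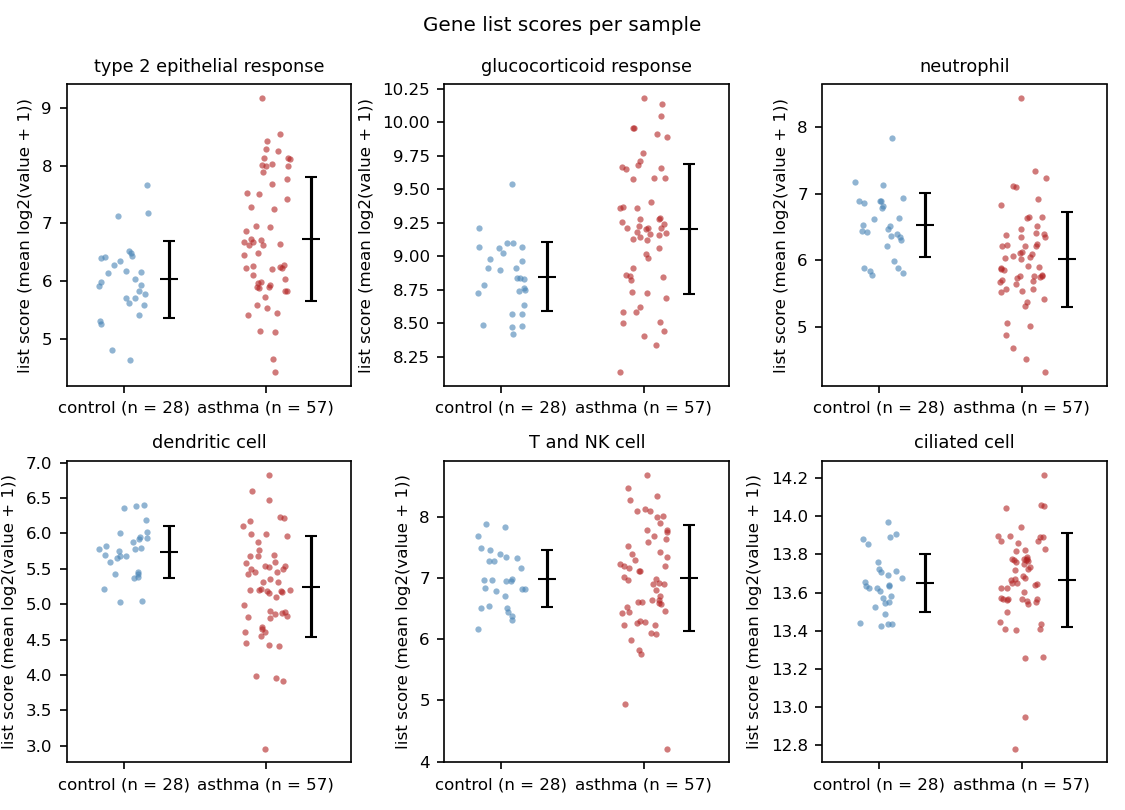
List score (mean log2(value + 1) of the members) of each sample for 6 gene lists in 28 control (blue) and 57 asthma samples (red). Black marks give the group mean and SD, with the type 2 SD at 1.07 in asthma and 0.66 in controls and the T and NK difference at 0.01 ± 0.14 (SE).

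The last comparison asked which of a set of other programs, fixed beforehand, moved with the type 2 score from sample to sample inside a group. The set held mast cell, eosinophil, mucous, ciliated, basal, interferon, NF-kB and glucocorticoid lists. Relations of the remaining lists with the score were not computed, so nothing is known of them here. Within the set, mast cell markers followed it most closely. In asthma, Pearson's r was 0.665 and Spearman's rho 0.684 over 57 samples (adjusted permutation p = 0.00016 for each, from the smallest p the permutations can give, 1e-05), and r was 0.639 without the 2 samples farthest from the median type 2 score. In controls, r was 0.537 and rho 0.566 over 28 samples (raw permutation p = 0.00336 and 0.00203, adjusted p = 0.0179 and 0.0162), and 0.575 without the 2 farthest. Whether the relation differs between the groups was not tested. Of 16 relations computed, 5 passed for Pearson's r and 4 for Spearman's rho.

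Within asthma, mucous and goblet markers followed the type 2 score with r = 0.396 and rho = 0.356 (raw permutation p = 0.00239 and 0.00691, adjusted p = 0.0179 and 0.0369), and r was 0.312 without the 2 farthest samples. Eosinophil markers followed it with r = 0.335 and rho = 0.338 (raw permutation p = 0.0105 and 0.0109, adjusted p = 0.0335 and 0.0435), and r was 0.323 without the 2 farthest. The eosinophil relation lost its call without the 3 far libraries (r = 0.282, adjusted p = 0.122), given ciliated and basal scores (partial r = 0.248, adjusted p = 0.167), and without the 16 libraries that skip whole numbers (r = 0.313, adjusted p = 0.0899). NF-kB and interleukin-17 targets had r = -0.352 (raw permutation p = 0.00616, adjusted p = 0.0246) but rho = -0.251 (adjusted p = 0.136), and r of -0.207 without the 2 farthest samples (permutation p = 0.131), so this relation rests on those samples. It kept its call for r without the 3 far libraries (r = -0.373, adjusted p = 0.0222), given ciliated and basal scores (partial r = -0.429, adjusted p = 0.0052), and without the 16 libraries (r = -0.401, adjusted p = 0.0227). In controls the eosinophil, mucous and NF-kB relations had r = 0.309, 0.202 and 0.00753 (adjusted permutation p = 0.196, 0.442 and 0.97). Without the 16 libraries the eosinophil r in controls was 0.489 (adjusted permutation p = 0.0559). Whether these relations differ between the groups was not tested. The mast cell relation in asthma had r = 0.681 in the first 49 columns and 0.632 in the last 36, while the mucous relation had 0.50 and 0.07 (permutation p = 0.00219 and 0.748) and the NF-kB relation -0.443 and -0.116 (permutation p = 0.00698 and 0.61). The eosinophil relation had 0.329 and 0.408 (permutation p = 0.0527 and 0.0562), and the mast cell relation in controls 0.594 and 0.399 (permutation p = 0.0236 and 0.159). Whether relations differ between the parts was not tested. Ciliated, basal, interferon and glucocorticoid scores passed in neither group, with r from -0.256 to 0.0286. Without the 2 farthest control samples the interferon relation went from r = -0.226 to -0.474 (unadjusted permutation p = 0.017) and the basal relation from 0.0286 to -0.259 (unadjusted permutation p = 0.201).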

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

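The 50 called genes, 12 lists by camera, 4 lists by permutation, 4 lists by spread and 5 relations were recomputed. Leaving out 16 libraries that skip whole numbers or 18 with any factor above the limit, the table part, the aryl hydrocarbon receptor and myeloid scores and sample quality weights were tests chosen after the data were seen. No list score or named gene that was called changed direction. Gene counts stayed within 1.5 times under TMM factors, quantile normalization, no filter, either pseudocount, robust empirical Bayes, library complexity and the table part as a covariate (42 to 62).

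Fewer genes were called among the genes above the median of the gene means (2, of them 1 named gene, and 1 list by permutation), after a rank-based transform (29, 15 named genes) and without 3 far libraries (30, 17 named genes, 60% higher in asthma against 46%). None were called with cell composition as covariates (0 genes, 0 named genes, 938 genes unadjusted), where 2 lists passed by permutation, type 2 and glucocorticoid response. None were called with myeloid scores as covariates (0 genes, 0 named genes, 496 unadjusted, and 1 list, eicosanoid synthesis, that is none of the 4). None were called without the 16 libraries (0 genes, 0 named genes, 1706 unadjusted, 1 list), without the 18 (0 genes, 0 named genes, 3 lists) or in the first 49 or 58 columns (0 genes, 0 named genes, 0 lists each). List counts given beside gene counts here are those of the permutation test. Camera with the preset correlation called 12 lists without the 16 and 12 without the 18. It called 10 in the first 49 columns and 10 in the first 58. The last 36 columns gave 482 genes and 7 lists, the last 27 columns 77 genes (17 named genes, 9 lists), the aryl hydrocarbon receptor score 90 genes, the first 2 residual components 819 genes (50 named genes, 7 lists) and quality weights 1494 genes (60 named genes), against 26 named genes as reported. Camera with an estimated correlation called 0 lists, fry 4 and the permutation test 4. For spread, the ratio of SDs called 7 lists, and 0 were called without the far libraries, without the 16 or without the 18. Causes were tested only for the 16 libraries, the residual components, the quality weights and the table parts. Robust empirical Bayes does not enter the list tests, and the planned count models were not run because the values are not counts.

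Leaving out the 16 libraries also lowers the sample size. With as many libraries of each group removed at random, 18 of 100 removals, the real one included, called 0 genes, and the others had a median of 9 and a highest count of 270, so a smaller sample may account for the loss. The residual components call as many genes in 19 of 100 splits of the samples (highest other 4731), so chance cannot be excluded for the 819 genes. These components are computed after the group is fitted, so they leave the fold changes as they were and only lower the residual spread. Genes were called this way in 47 of the other splits, against 2 without the components. The larger count may therefore come from the procedure itself. With quality weights 2 of 100 splits gave as many as 1494 (highest other 1570). That share is under 0.05, yet a random split called more, so a structure of the samples may add to the count.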

Other observations

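The tests of the table parts by random divisions and by list, of T and NK cells, and of column position were chosen only after the results were seen. The group difference in genes exceeded chance: 1 of 100 splits of the 85 samples into 57 and 28, the real one itself, called as many as 50 genes, and the highest other called 3. For the permutation test of list scores, likewise 1 of 100 splits called as many as 4 lists (highest other 2). For camera with the preset correlation, 14 of 100 splits called as many as 12 lists, and the highest other called 15, so chance cannot be excluded for that count. The other splits had a median of 7 lists, and 97 of them called any list. The adjusted p-values of camera with the preset correlation are thus too small here.

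Single genes outside the named ones also differed, and these were chosen after their values were seen. PDGFRA, a platelet-derived growth factor receptor of mesenchymal cells, was higher (log2 fold change 0.78 ± 0.18, limma adjusted p = 0.026), as was GDNF, a neurotrophic factor (0.73 ± 0.17, adjusted p = 0.0264). IRF8, a transcription factor of monocytes and dendritic cells, was lower (-0.76 ± 0.18, adjusted p = 0.0309), as were CCR1, a chemokine receptor of myeloid cells (-0.78 ± 0.19, adjusted p = 0.0383), and PLEK, the leukocyte and platelet protein pleckstrin (-0.85 ± 0.20, adjusted p = 0.0309). The second principal component of all genes, with 7.76% of the variance, differed between the groups (permutation adjusted p = 0.0027) and had r = 0.575 with the type 2 score and -0.626 with the monocyte and macrophage score.

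Neutrophil and dendritic cell markers were lower in asthma, with score differences of -0.51 and -0.49, but both lists lost their call with an estimated correlation (adjusted p = 0.0835 for each). No neutrophil marker passed over all genes, and without the 16 libraries both lists lost their permutation call (adjusted p = 0.232 for neutrophil and 0.08 for dendritic cell). Without the 18 only the neutrophil list of these 2 lost it (adjusted p = 0.231, against 0.0428). The T and NK difference lay 0.508 above the mean of both (SE 0.153), which argues against an equal fall of every leukocyte kind. Both lists were picked because they were low, so part of that gap is built in and the SE leaves this out. The monocyte and macrophage score was lower as well (-0.505), so a lower total share of leukocytes stays open. Library complexity is argued against as the whole cause, since both lists stayed past the threshold with it as covariate (larger adjusted p = 0.0142). Table position stays open: with it as covariate the larger adjusted p was 0.0102. The groups are spread nearly evenly over the 2 parts, so that covariate can move little. Inside the first 58 columns (44 asthma, 14 control) the groups lie mostly in separate runs of columns. An effect of column order cannot be told apart from the disease there, by this covariate or by tests inside a part. The dendritic cell difference was -0.238 in the first 49 columns and -0.769 in the last 36 (adjusted p = 0.626 and 0.0145), the neutrophil difference -0.443 and -0.615 (adjusted p = 0.499 and 0.0267), and a test of the difference between the parts gave permutation p = 0.0636 and 0.566. With the boundary at column 58 the dendritic cell differences lay closer together, at -0.336 and -0.526 (permutation adjusted p = 0.663 and 0.023). The neutrophil differences were -0.483 and -0.611 there (permutation adjusted p = 0.474 and 0.0134). A candidate explanation that stays open is glucocorticoid exposure, which no label gives: inside asthma the glucocorticoid score had r = -0.299 with the mean of both scores (rho = -0.346, permutation p = 0.0232 and 0.00865, n = 57, r = -0.30 without the 2 farthest samples). This relation may equally reflect disease severity or cell make-up, and neither these nor the disease itself could be tested apart from it.

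The number of called genes differed along the table: limma called 0 genes in the first 49 columns and 482 in the last 36. Such counts do not by themselves show that the asthma difference is unlike in the parts. For the 4 lists called by permutation, a test of the difference between the parts gave adjusted permutation p from 0.339 to 0.969. Of 100 random divisions of the same sizes within each group, 1, the real one, gave as many genes in a part (highest other 429), and 4 gave as many as the 2889 genes with an unadjusted interaction p under 0.05 (1 gene adjusted). Because several boundaries were looked at, these shares are too small, and with the boundary at column 58 the counts were 0 and 77. Without the libraries that skip whole numbers the last part called 55 genes and the first 0, and fewer samples and the loss of those libraries cannot be told apart there. An unlabelled batch or a difference in the patients may lie behind it, and no biological explanation was tested.

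All 18 aryl hydrocarbon receptor and oxidative stress genes had negative fold changes, but the difference of medians was only 39.6% of the difference of means (-0.167, 95% interval -0.47 to 0.0734, against -0.423), so some samples with high scores may carry the mean, though 0 controls lay above the highest asthma score and such samples occur in asthma too. Smoke or another exposure unevenly present among the samples is a candidate source that no label allows to be tested. A lower myeloid content stays open: with the monocyte and macrophage score as covariate 94.4% of the difference was kept, with an interval from 27% to 129%, too wide to decide.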
